A study of Solanum lycopersicum with 9 samples.

How the data were processed

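Messenger RNA libraries were made from tomato leaves of 3 groups (control, partial defoliation, partial shading), with 3 biological replicates each per the series' design text. Per the labels' protocols, seedlings were raised in a growth chamber and moved to pots in a greenhouse, RNA was extracted with an RNeasy Plant Mini kit, and libraries were made with an Illumina TruSeq RNA kit, which does not mark strand. The labels name leaf mesophyll as the cell type, while the protocol describes extraction from leaves. Whether the replicates of different groups with the same number shared a day or tray is not given in the sources used here.

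The deposited values are expected counts per gene from RSEM, whole numbers in the deposited table. Per the submitters' processing notes, the tools used were Trim Galore (read trimming), STAR (alignment), RSEM (counting) and DESeq2; their versions, the genome build and the annotation are not given in the sources used here. RSEM divides reads that match several genes between them by estimation, so counts of near-identical gene copies are uncertain, and without strand the reads of overlapping or antisense genes cannot be told apart.

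CPM values (counts scaled to library size) were computed from the deposited counts with the effective library sizes of the TMM method. Genes were kept by filterByExpr with the groups as design, which left 20480 of 23195 genes (88.3%) and 99.96% of counts. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust estimation and the default fitting method of that version, on all 9 libraries in one fit with a coefficient per group and no further covariate, so that the groups shared one estimate of the spread (common biological coefficient of variation 0.23). P-values were adjusted by the Benjamini-Hochberg method over all tested genes and genes below 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. A group without counts was given a floor of 3 counts over its 3 libraries, which covers counting error only. Bounds on a fold divide the mean of the other group by this floor and do not cover the spread between replicates. The 3 comparisons were defoliation against control, shading against control and shading against defoliation.

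Total counts per library lay between 17617138 and 31012772. Tested on data simulated from the real means and library sizes with 200 changed genes, the test recovered 6%, 37.9% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold in the setting of defoliation against control (20293 genes), with 8 false calls among 96. It recovered 7.6%, 44.8% and 89.4% in that of shading against control (20268 genes), with 10 false calls among 104, and 6.2%, 53.7% and 85.9% in that of shading against defoliation (20276 genes), with 6 false calls among 101. Simulated counts had the spread fitted to each gene's abundance, not each gene's own spread. The adjusted threshold also depends on how many genes change, so these shares do not give the power in the real data.

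The rule for named genes, set before the data were examined, took from each comparison the called genes with the largest positive and negative log2 fold changes, among those with all 3 libraries of one group beyond all 3 of the other and at least 5 CPM in the higher group. It required a described gene product and named 5 per direction. Since 0 of 23195 identifiers matched the reference gene table (assembly SLM_r2.1), the requirement of a product could not be applied and the number was lowered to 2 per direction. For the same reason the gene lists fixed beforehand, those for photosynthesis and for other cell types included, could not be tested, and the part of the rule that named list members was not used.

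The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile scaling, other filters on low counts, fits of the compared groups alone, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library in turn. Thinning of all libraries to one depth, the newer quasi-likelihood method of the same edgeR version, a comparison of the 6 treated with the 3 control libraries and all work on the most abundant genes and on neighbouring genes were added after seeing the data. A first run used the newer quasi-likelihood method; the version's default was then taken as the main test, because the test fixed beforehand named no other setting, and this choice was made with the counts of both known.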

Results

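Leaf RNA was sequenced from tomato plants (Solanum lycopersicum) of the processing cultivar M82 in 3 groups of 3 biological replicates. In the partial defoliation group every leaf except the one to be measured was cut off. In the partial shading group aluminium foil covered all leaves other than the youngest fully expanded leaf. Both treatments began 1 week after the first flowers opened and were made to lower the ratio of source (sugar-exporting) to sink (sugar-importing) tissue. RNA came from the remaining leaf and from matching leaves of untreated control plants. The labels of the treated libraries also carry the number 48, whose unit they do not state. The labels of the control libraries carry no such number. What it marks therefore cannot be told apart from the treatments in any comparison with control.

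The count table held 23195 genes, 3 of them at 0 in all 9 libraries. Total counts were 25586633, 25202105 and 27988818 in the control libraries, 26058491, 31012772 and 29791000 in the defoliation libraries and 28159415, 29758980 and 17617138 in the shading libraries. A count of 3 corresponded to between 0.0967 and 0.17 CPM (counts scaled to library size), depending on the library. Shading replicate 3, the shallowest library, held 1657 genes at 0, against 334 to 711 in the other 8 libraries and at most 888 in any of those thinned to its total. Rank correlations across genes within groups ranged from 0.9767 to 0.9889, and no pair of replicates agreed within sampling noise. The identifiers are not paired with gene names or products in the table, and 0 of 23195 matched the gene table of the reference, so genes are given by identifier and no gene function is assigned.

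The first principal component of log2 CPM carried 45% of the variance and placed the 3 control libraries at -66.1, -60.2 and -89.5, apart from the 6 treated libraries at 25.6 to 61.4. The second component, with 18.5%, placed the defoliation libraries above the shading libraries, and shading replicate 3 lay at -83.1.

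**Figure D1:**
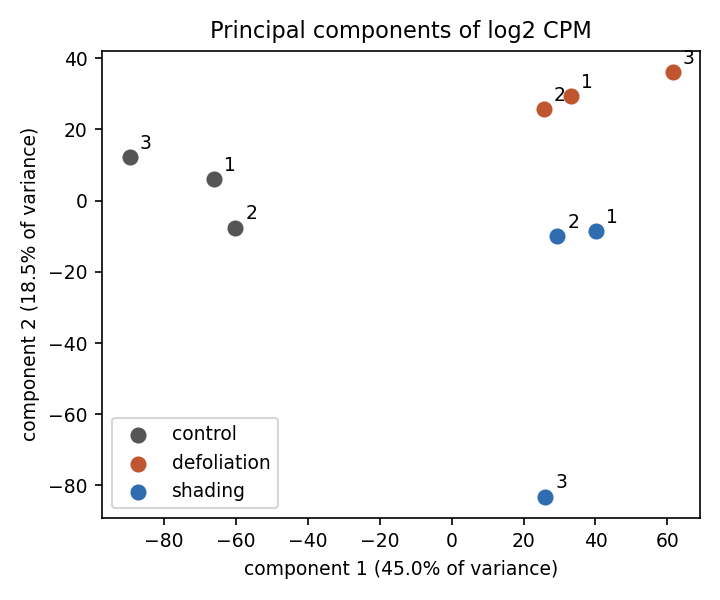
Scores of the 9 libraries on the first (45% of variance) and second (18.5%) principal component of log2 CPM, in arbitrary units, one point per library, coloured by group and numbered by replicate. The 3 control libraries lie below -60 on the first component and the 6 treated libraries above 25.

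The comparison of defoliated with control plants asks which transcripts of the remaining leaf differ once all other leaves are gone. Levels of 7015 of the 20480 genes tested (34.3%) differed after defoliation, with 3863 higher and 3152 lower than in control leaves. The excess of rising genes depended on scaling, as upper-quartile factors gave 3537 higher and 3567 lower. Increases were the larger changes, with a median log2 fold change of 1.02 among the genes that rose and -0.76 among those that fell. At least 2-fold changes were seen for 1967 genes that rose and 967 that fell, and at least 4-fold changes for 494 and 163. Solyc05g007830.3 rose from 11.1 ± 3.44 CPM in control leaves to 271 ± 84.2 CPM after defoliation (SD, n = 3), a 24.5-fold difference (log2 fold change 4.61 ± 0.44 SE, adjusted p = 0.000405, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

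The other genes selected for this comparison were more variable. Solyc03g082975.1 had no counts in the 3 control libraries and 9.98 ± 5.63 CPM after defoliation (SD, n = 3, edgeR adjusted p = 0.0225). That mean is at least 275-fold higher when 3 counts over the control group are taken as the floor, but defoliation replicate 2 stood at 3.48 CPM. The call was lost without control replicate 3, defoliation replicate 1 or defoliation replicate 3, with fitted log2 fold changes of 11.06, 10.82 and 10.78. The bound was 183-, 189- and 179-fold without control replicates 1, 2 and 3, and 230-, 365- and 231-fold without defoliation replicates 1, 2 and 3. Solyc01g100200.3 stood at 5.79, 3.76 and 65.69 CPM in the control libraries and at 0.45 ± 0.78 CPM after defoliation (log2 fold change -5.90 ± 1.74 SE, edgeR adjusted p = 0.0315). Without control replicate 3 its log2 fold change was -3.47 and no longer passed, and it also failed without defoliation replicate 2 (-5.27) or 3 (-5.28) and with DESeq2 (-5.80). Without defoliation replicate 1 the defoliation libraries held no counts of it (fitted -12.40). Solyc06g007190.3 stood at 1.87, 1.23 and 117.15 CPM in the control libraries and at 0.73 ± 0.22 CPM after defoliation (log2 fold change -5.77 ± 1.76 SE, edgeR adjusted p = 0.0362). Its log2 fold change was -1.08 without control replicate 3, and it failed without any 1 of the 3 defoliation libraries (-5.81, -5.54 and -5.98) or the 3 shading libraries (-5.77 each), as well as with only the control and defoliation libraries in the fit (-5.77).

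For defoliation against control 9197 genes had an unadjusted edgeR p below 0.05, where uniform p-values would give 1024. The 3 defoliation libraries did not overlap the 3 control libraries in CPM for 51.9% of genes, against 10% by chance. Without defoliation replicate 3 the number of genes that fell was 2077.

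The comparison of shaded with control plants asks the same question with the other leaves darkened but still attached. Under shading 6182 genes differed (30.2% of those tested), of which 3283 rose and 2899 fell relative to control leaves. Their median log2 fold changes were 0.94 and -0.78. At least 2-fold changes were seen for 1528 genes that rose and 962 that fell, and at least 4-fold changes for 264 and 221. Solyc06g061200.1 rose from 0.187 ± 0.172 CPM to 17.3 ± 7.57 CPM (SD, n = 3), a 92.6-fold difference (log2 fold change 6.53 ± 0.70 SE, edgeR adjusted p = 0.000541), and stood at 4.18 ± 2.21 CPM after defoliation. Its log2 fold change was 7.58 without control replicate 2, which held the most counts of it among the controls.

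A further gene selected for its rise under shading, Solyc06g068290.1, went from 0.229 ± 0.367 CPM in control leaves to 6.37 ± 1.56 CPM (SD, n = 3; log2 fold change 4.82 ± 0.81 SE, edgeR adjusted p = 0.00281), and stood at 5.41 ± 1.21 CPM after defoliation. That fold rests on control replicate 2 (0.65 CPM, against 0 and 0.03 in the other controls), with a fitted log2 fold change of 8.19 without it and 4.23 without control replicate 1. Solyc06g062540.3 stood at 3.49, 1.27 and 13.1 CPM in the control libraries and had no counts in the 3 shading libraries, which is at least 138-fold lower with 3 counts over the shading group as the floor (edgeR adjusted p = 0.00508). The bound was 55-fold without control replicate 3, 87-fold without shading replicate 1 and 81.4-fold without shading replicate 2. Solyc01g100200.3 fell to 0.30 ± 0.52 CPM under shading (log2 fold change -6.81 ± 1.94 SE, edgeR adjusted p = 0.0313). This last call failed without control replicate 3 (-4.32), shading replicate 1 (-6.13) or shading replicate 2 (-6.05), without shading replicate 3, which left shading at 0 (fitted -12.48), with DESeq2 (-6.35), and with only the control and shading libraries in the fit (-6.82).

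At an unadjusted p below 0.05 there were 8525 genes for shading against control, with 1024 by chance. Group values did not overlap for 46.3% of genes, against 10% by chance. Without control replicate 3 the number of genes that fell was 1922, and without shading replicate 3 there were 3032 genes that rose and 2276 that fell.

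In both treatments largely overlapping sets of genes differed from control in one direction. Both have the same controls and a label number that the controls lack, so the overlap cannot be assigned to the treatments alone. Of the genes called against control, 2588 rose in both treatments and 2022 fell in both, 4610 in all, while 3 genes were called in opposite directions. Independent lists of the same lengths would share 619 rising and 446 falling genes and hold 1052 genes in opposite directions. The genes that rose in both had median log2 fold changes of 1.09 after defoliation and 1.02 under shading, and those that fell in both -0.81 and -0.80. Solyc05g007830.3, described above for defoliation, rose to 163 ± 88.8 CPM under shading (SD, n = 3; log2 fold change 3.88 ± 0.42 SE, edgeR adjusted p = 0.000593). Solyc03g082975.1 reached 12.68, 4.41 and 0 CPM in the 3 shading libraries, on average at least 157-fold above control (edgeR adjusted p = 0.0356), a call that was lost without any 1 of the 3 control libraries (fitted log2 fold changes 10.29, 10.30 and 10.28), the 3 defoliation libraries (10.29, 10.25 and 10.26) or shading replicate 1 (8.99) or 2 (10.44). Its bound was 60.9-fold without shading replicate 1, 236-fold without shading replicate 3 and 105-, 108- and 102-fold without control replicates 1, 2 and 3. With only the control and shading libraries in the fit, Solyc03g082975.1 did not pass the filter on low counts and was not tested.

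Because both comparisons used the same 3 control libraries, some similarity arises with no effect at all. In 20 simulations of unchanged groups against shared controls, no gene was called in both comparisons. With no effect simulated, almost no calls can arise, so this does not show how much the shared controls add to the overlap of calls. The simulated counts had the spread fitted to each gene's abundance, not each gene's own spread. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.81 against 0.497 in the simulations, and the covariance was 0.605 against 0.059, a difference of 0.546. The share of genes with one sign in both comparisons was 82.1%, against 66.7% in the simulations. The 3 control libraries are too few for a split that keeps 2 in each part, so part of the excess may come from the shared controls.

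**Figure D2:**
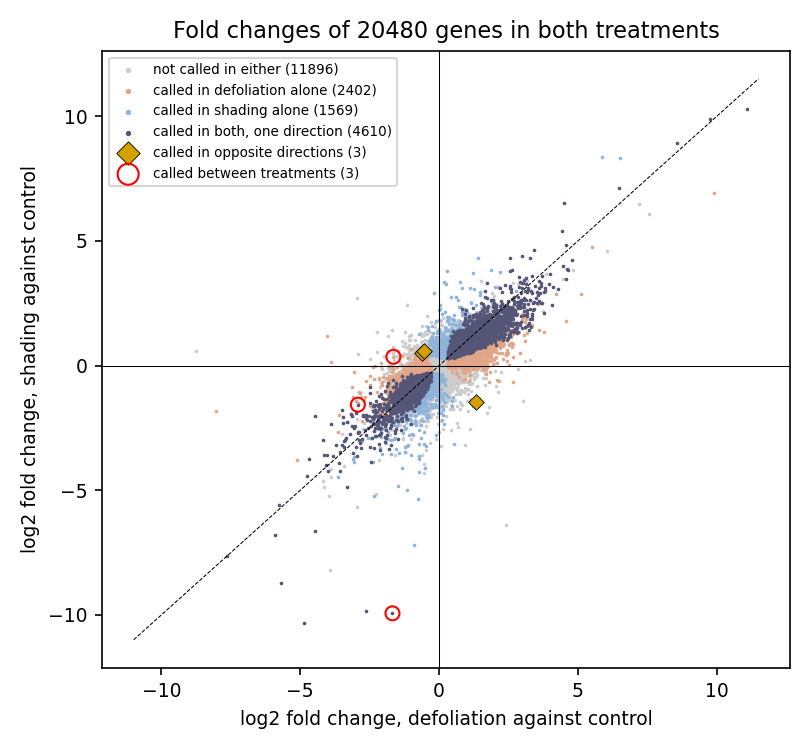
Log2 fold change of each of 20480 tested genes in shading against control (vertical axis) and in defoliation against control (horizontal axis), coloured by the calls in each comparison, with equality dashed. The 4610 genes called in one direction in both treatments lie along the dashed line, and the 3 called in opposite directions (diamonds) and the 3 called between the treatments (rings) are marked. Fitted values of genes without counts in a group depend on the prior count.

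A call after 1 treatment alone is not by itself a difference between the treatments, which the direct test asks for. Of 2402 genes called in defoliation alone, 1 was called by edgeR in the direct comparison, and of 1569 genes called in shading alone, 0 were. As edgeR called 3 genes there in all, these counts were low for any class and do not tell the classes apart. DESeq2 called 1014 of all genes there, which were not divided by class. An unadjusted direct edgeR p below 0.05 was found for 582 of the 1274 genes that rose and 429 of the 1128 that fell in defoliation alone. In shading alone it was found for 365 of the 693 that rose and 290 of the 876 that fell. Lower shares had it among genes that rose in both (453 of 2588, 17.5%) or fell in both (209 of 2022, 10.3%). Among genes called in neither, 1076 of 11896 (9%) had it. The classes were formed from the same libraries as the direct comparison, so these shares are descriptions and not tests.

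The direct comparison of shading with defoliation asks whether attached but darkened leaves leave another transcript profile in the remaining leaf than removed ones. Expression of 2 genes was higher under shading and of 1 gene lower, and all 3 are named here. The last, Solyc02g070010.1, lay outside the selection rule and was chosen after its values were seen. Solyc06g051940.3 stood at 25.4 ± 4.91 CPM in control leaves, 8.12 ± 1.13 CPM after defoliation and 32.4 ± 5.64 CPM under shading (SD, n = 3), with a log2 fold change between the treatments of 2.00 ± 0.19 (SE, edgeR adjusted p = 0.0143). It fell after defoliation (log2 fold change -1.65 ± 0.19 SE, edgeR adjusted p = 0.000523) and did not pass under shading (0.35 ± 0.18, edgeR adjusted p = 0.164). Solyc01g096320.3 fell from 123 ± 3.02 CPM in control leaves to 16.2 ± 1.49 CPM after defoliation and 41.4 ± 8.33 CPM under shading, a log2 fold change between the treatments of 1.36 ± 0.15 (SE, n = 3, edgeR adjusted p = 0.0287). Solyc02g070010.1 stood at 4.55 ± 0.18 CPM in control leaves and 1.41 ± 0.42 CPM after defoliation and had no counts in the 3 shading libraries. With 3 counts over the shading group as the floor it was at least 105-fold lower under shading than in control leaves (edgeR adjusted p = 0.000265) and at least 32.6-fold lower than after defoliation (edgeR adjusted p = 0.0212). These bounds were 66.4- and 20.6-fold without shading replicate 1 and 62.2- and 19.3-fold without shading replicate 2, since fewer libraries raise the floor.

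These direct calls depended on the test and on single libraries. DESeq2 called 576 genes higher and 438 lower, and limma-voom 2 and 1, while 3407 genes had an unadjusted p below 0.05 in edgeR. Uniform p-values would give 1024, but other splits of the same 6 libraries gave up to 2203. The shading and defoliation libraries did not overlap in CPM for 21.8% of genes, against 10% by chance, a share not computed for the other splits. With only the shading and defoliation libraries in the fit, 1 gene was higher and 2 lower, and of the 3 genes named here Solyc06g051940.3 alone was among them. With the replicate number as a block, 0 genes were higher and 0 lower. No gene was called without defoliation replicate 2 or without defoliation replicate 3, and between 1 and 5 were called without any other treated library. Without control replicate 1 there was 1 gene higher and 0 lower, without control replicate 2 there were 1 and 1, and without control replicate 3 there were 3 and 2. The log2 fold change of Solyc06g051940.3 was 1.89 and 2.03 without defoliation replicates 2 and 3, the single libraries whose removal ended its call. In simulated data for this comparison the test recovered 53.7% of genes changed 2-fold and 85.9% of those changed 4-fold, so that absence from the calls does not show equal expression.

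**Figure D3:**
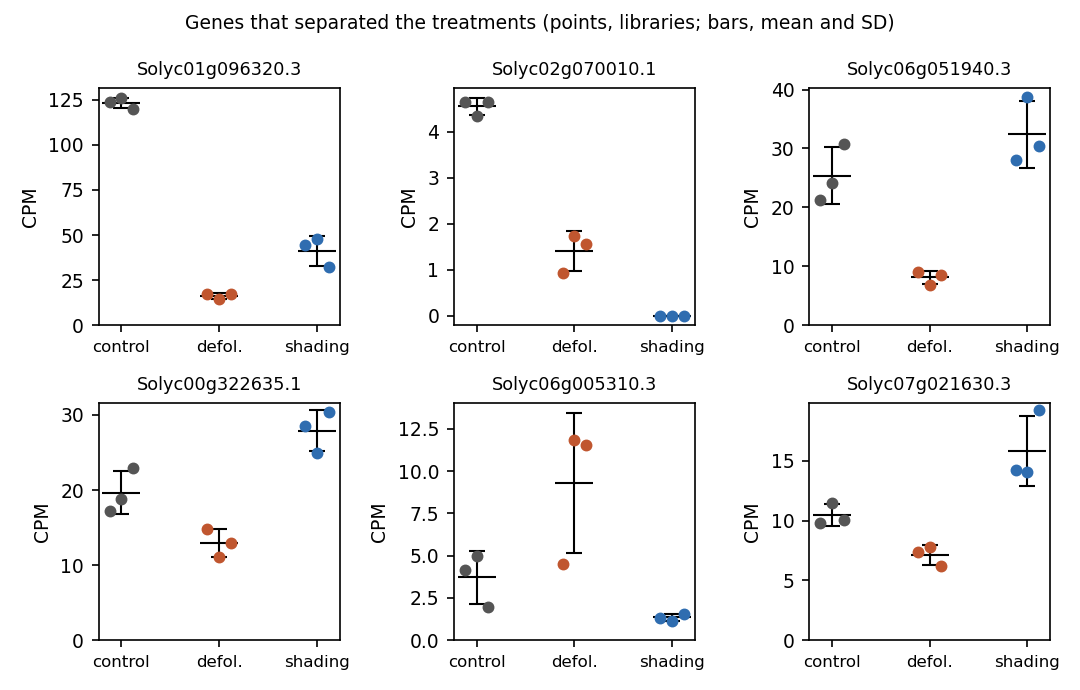
CPM of the 3 genes called between shading and defoliation (upper row) and of the 3 genes called in opposite directions against control (lower row), one point per library, with the mean and SD of each group (n = 3) as horizontal and vertical bars. Solyc02g070010.1 has no counts in the 3 shading libraries, and Solyc01g096320.3 falls from 123 CPM in control leaves to 16.2 CPM after defoliation and 41.4 CPM under shading.

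The 3 genes called in opposite directions against control, named because of that count after their values were seen, did not pass in the direct comparison by edgeR with all libraries. Solyc00g322635.1 stood at 19.7 ± 2.93, 12.9 ± 1.88 and 27.9 ± 2.77 CPM in control, defoliation and shading leaves (SD, n = 3; direct log2 fold change 1.11 ± 0.16 SE, edgeR adjusted p = 0.0836). Solyc07g021630.3 stood at 10.5 ± 0.93, 7.11 ± 0.83 and 15.9 ± 2.93 CPM (direct log2 fold change 1.15 ± 0.17 SE, edgeR adjusted p = 0.0871). Solyc06g005310.3 went the other way, with 3.71 ± 1.57, 9.30 ± 4.14 and 1.35 ± 0.19 CPM (direct log2 fold change -2.80 ± 0.44 SE, edgeR adjusted p = 0.0889). DESeq2 called each of the 3 in the direct comparison, with log2 fold changes of 1.12, 1.17 and -2.78. In edgeR Solyc06g005310.3 passed the direct comparison without defoliation replicate 1 (-3.13). Against control, Solyc00g322635.1 lost its defoliation call without control replicate 3 (-0.48) and its shading call without control replicate 1 (0.42) or 2 (0.50) or shading replicate 1 (0.49) or 3 (0.44). Solyc07g021630.3 lost its defoliation call without control replicate 2 (-0.48) or defoliation replicate 1 (-0.58) or 3 (-0.46), and its shading call without control replicate 1 (0.55) or 3 (0.57) or shading replicate 3 (0.44). Solyc06g005310.3 lost its defoliation call without control replicate 1 (1.42) or 3 (1.02) or defoliation replicate 2 (1.12) or 3 (1.15) or with only the control and defoliation libraries in the fit (1.32), and its shading call without control replicate 1 (-1.37) or 2 (-1.17) or any 1 of the 3 shading libraries (-1.46, -1.37 and -1.57).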

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

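DESeq2 and limma-voom were alternatives planned beforehand, but their counts were taken as a test of why few genes passed after they had been seen. The following were also chosen after seeing the data: all tests on the 100 most abundant genes, of which those of scaling and of depth used results already seen, the thinning to one depth, and the comparison of the 6 treated with the 3 control libraries. The 3 genes called between shading and defoliation stood out because the treatments themselves differed in the direct test, with log2 fold changes (shading minus defoliation) of 2.00 for Solyc06g051940.3, 1.36 for Solyc01g096320.3 and a fitted -8.26, no bound, for Solyc02g070010.1, at least 32.6-fold lower under shading. Solyc01g096320.3 kept its direct call without control replicate 3 or shading replicate 3 and lost it without any other single library (values from 1.24 to 1.40). Solyc02g070010.1 kept its call without control replicate 3, defoliation replicate 1 or shading replicate 3 and lost it without any other single library (fitted values from -8.27 to -8.05). Solyc06g051940.3 lost its call without defoliation replicate 2 (1.89) or 3 (2.03). With only the shading and defoliation libraries in the fit, Solyc06g051940.3 kept its call (2.02), and Solyc01g096320.3 (1.38) and Solyc02g070010.1 (fitted -8.23) lost theirs. All 3 lost their direct calls with the replicate number as a block (1.99, 1.34 and fitted -8.23 in the same order).

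Other splits of the libraries bear on whether chance alone gave the counts. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each case the real split, 1 of 10, gave the highest value. Defoliation against control called 7015 genes and the other splits at most 0. Shading against control called 6182 and the other splits at most 0. Shading against defoliation called 3 genes and the other splits at most 1, or 1014 and at most 265 with DESeq2. The 6 treated libraries against the 3 controls called 7112 genes, and the highest other of the 84 splits called 2. This argues against a chance split, but the comparison was chosen after seeing the data. Splits also cannot separate the treatments from what the label number of the treated libraries marks.

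A first pattern is that 3 genes were called between shading and defoliation although 3407 had an unadjusted p below 0.05 (up to 2203 in other splits of the 6 libraries). A wide spread of shading replicate 3 stays open: 3 genes were called without that library, which lies within the 0 to 5 called without another treated library and, against the reading set beforehand, decides nothing, since leaving it out also leaves shading with 2 libraries, while the defoliation calls went from 3863 higher and 3152 lower to 4030 and 3273. Unequal depth stays open as well: thinning all libraries to one depth gave 4 calls, but it can only remove counts and cannot bring back calls lost to low depth, so that a low number there, read beforehand as speaking against depth, decides nothing. The choice of test also stays open as an explanation, because DESeq2 called 1014 genes on the same counts while limma-voom called 3. A biological reading, that the treatments differ in more genes than the quasi-likelihood test calls, may also hold and was not separated from a more permissive test.

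A second pattern is in the 100 most abundant genes by mean CPM over all libraries. Against control, 43 were higher and 11 lower under shading (5 lower without control replicate 2, 6 without shading replicate 2, 7 without control replicate 1 or shading replicate 1), and 13 were higher and 24 lower after defoliation (8 higher without control replicate 1, 14 lower without control replicate 2). Between the treatments edgeR called 0 of the 100, but 66 had an unadjusted p below 0.05, each of them higher under shading, and the median log2 fold change was 0.49. Their share of all counts was 28.5% ± 1.25 in control, 26.7% ± 2.47 in defoliation and 33.1% ± 1.40 in shading libraries (SD, n = 3; exact two-sided permutation p = 0.1 for shading against either group, the smallest that 3 against 3 allows, and 0.5 for defoliation against control). The list differed from other genes between the treatments in camera with a preset correlation (adjusted p = 2.9e-25), but not with an estimated correlation (adjusted p = 0.237). The difference was not limited to the list. Of the 900 genes next in abundance, 230 were higher and 41 lower under shading than after defoliation (unadjusted edgeR p below 0.05). Their median log2 fold change was 0.15 (camera adjusted p = 6.6e-08 with preset and 0.237 with estimated correlation). Medians were -0.03 in the next 9000 genes and -0.06 in the other 10480. The tests that follow used the 100 genes only and did not ask why the difference followed abundance.

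Among technical explanations for the abundant genes, a single aberrant library is argued against by a median of at least 0.37 without any 1 of the 6 treated libraries, the lowest being without shading replicate 3. Scaling on genes below rank 1000 gave a median of 0.52. This value follows from the medians of -0.03 and -0.06 in the classes below that rank, so it is no separate test. A scaling factor moves all genes of a library alike and would not set the classes apart, but a bias that follows abundance was not tested. Unequal depth is argued against by a median of 0.49 with all libraries thinned to one depth. Without shading replicate 3, the shallowest library, 0.37 remained. The other splits of the 6 treated libraries gave a median of at most 0.28 in size against 0.49, in 10 splits that are too few for a share under 0.05. Chance therefore stays open, and a difference between the treatments in abundant transcripts may be offered as a hypothesis only.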

How the results depend on the processing

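The newer quasi-likelihood method and the thinned counts were chosen after seeing the data. The counts of genes against control and the overlap of both treatments stayed within 1.5-fold of the reported values with DESeq2, limma-voom, other scalings, other filters, thinned counts and the newer method. They changed with a minimum log2 fold change of 1, which by construction keeps fewer genes: 1967 higher and 967 lower after defoliation, 1528 and 962 under shading, and 1663 in both. Shading against defoliation moved more. DESeq2 called 576 higher and 438 lower, the fit of the groups compared alone 1 and 2, and the newer quasi-likelihood method 2 and 0; the cause was not tested. Leaving out 1 library in turn gave 2077 to 3273 genes lower after defoliation (lowest without defoliation replicate 3), 1922 to 2920 lower under shading (lowest without control replicate 3), and 0 to 3 higher and 0 to 4 lower between the treatments. Whether replicates with the same number were paired is not given. Correlations of their deviations between groups ran from -0.19 to 0.14, and not every library matched its own number best. Among the defoliation libraries, shading replicates 1 and 2 did so (0.141 and 0.136) and shading replicate 3 did not (0.007). Among the controls, shading replicates 1 and 3 did so (0.068 and 0.042) and none of the defoliation libraries did. Pairing is therefore not excluded. With the replicate number as a block there were 3427 genes higher and 2633 lower after defoliation, 2850 and 2382 under shading, 3863 in both and 0 and 0 between the treatments, and 9 of the 28 calls of named genes were lost, the 3 between the treatments included. The other lost calls were Solyc06g007190.3 and Solyc06g005310.3 in both comparisons with control, Solyc07g021630.3 after defoliation and Solyc03g082975.1 under shading. Only the 28 results called in the main fit could fall below the threshold in a refit, and up to 10 of them did so in 1 setting (without defoliation replicate 3). Refits without an adjusted p were not counted. Among these were Solyc06g007190.3 with DESeq2 and Solyc03g082975.1 under shading with the compared groups alone. Of 501 recomputed fold changes of named genes 408 kept direction and side of the threshold, 84 fell below it, 6 rose above it and 3 changed sign, none of these 3 past the threshold in either fit. Those 3 were shading against defoliation for Solyc01g100200.3 (5.59 without defoliation replicate 1; range without 1 library -6.58 to 5.59) and for Solyc06g007190.3 (-0.05 and -0.51 without defoliation and shading replicate 2; range -0.51 to 0.44), genes with 14 to 66 counts over each treated group; the cause was not tested. The tests of gene lists planned beforehand were not run, since no identifier could be tied to a product. In simulated data 6% to 7.6% of genes changed 1.5-fold were recovered at these depths with 3 libraries per group. The simulations of defoliation and of shading against control gave 96 and 104 calls, while the real comparisons gave 7015 and 6182. The adjusted threshold depends on how many genes change, so these shares do not give the power in the real comparisons with control. Depth was not varied in the simulations. Thinning to the lowest total left 3706 genes higher after defoliation and 3160 under shading.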

Other observations

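All analyses here, of gene order and of shading replicate 3, were chosen after seeing the data, and the 2 tests on shading replicate 3 were set up after their results were seen. Gene order was taken from the numbers in the identifiers, on the assumption that these follow position along a chromosome. No chromosome number stood apart in the share of rising among called genes (adjusted p = 0.961 in Fisher's exact tests of 13 identifier classes in each of 2 comparisons).

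Genes next to each other in identifier order were called in one direction more often than their numbers would give. Defoliation against control held 1544 such adjacent pairs, while 1000 shuffled orders within chromosomes gave 1211 on average and at most 1301, which argues against a chance order. Shading against control held 1207 pairs, with at most 1019 in shuffled orders. Runs of at least 4 such genes numbered 79 after defoliation (at most 51 in shuffled orders) and 43 under shading (at most 34). At 5 places apart the excess had ended, with 1225 pairs after defoliation inside the shuffled range of up to 1309. That is what reads shared between adjacent copies or overlapping genes would give, so this technical explanation stays open, and neighbouring genes that are regulated together may give the same. The hypothesis of joint regulation was therefore not separated from shared reads.

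Shading replicate 3 held 1657 genes at 0, and the other libraries thinned to its total at most 888. Its highest rank correlation was with a shading library, 0.9823, which exceeded the highest with another group by 0.0094. Not every treated library was closest to its own group. Shading replicate 2 and defoliation replicate 2 correlated best with each other (0.9872). Their best values within their own groups were 0.9863 with shading replicate 1 and 0.9864 with defoliation replicate 1. These are given as values, and no biological explanation was tested.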
